A study of Mus musculus with 2 samples.

How the data were processed

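DNase-seq was measured in whole testis of 10-day-old male B6CASTF1/J mice, 1 group with 2 biological replicates, per the labels. For each library the authors deposited 2 peak lists, a footprint list and a per-base cut-rate list, all made from the filtered mm10 alignments of that library alone, per the file listings. The programs, versions and thresholds behind these lists are not given in the sources used here. The deposited peak value is the authors' own peak height, a signal. All heights were whole multiples of a step that differed between libraries, within 0.1 step, so each library had been divided by a constant of its own, and whether that constant is the read depth is not stated. The deposited lists gave no p-value for peaks and no summit (the summit column is 75 throughout), so windows were centred on the middle of the peak. The values of the deposited footprint lists are of another kind, the constant 0.01, and only positions were used. The deposited cut-rate lists hold a false discovery rate (a q-value, in the class of p-value units) up to 0.05. The text listings of the libraries hold no measurement and were not used for values. Read totals are not given, so depth is unknown.

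Choices made before the data were examined were the comparisons, the 23 gene lists, the 30 motifs, the rule for named items and most alternatives. The shorter peak list of each library was the main one. Genome and annotation were the GRCm38.p6 assembly and GENCODE vM21, the same build as the files, and it was checked that every interval ended inside its chromosome. Promoters were windows of 500 bp on either side of any of 54361 annotated starts of 21853 protein-coding genes. Peaks were assigned to promoter, exon, intron and intergenic DNA in that order. Gene lists covered Sertoli cells, undifferentiated and differentiating spermatogonia, germ line and piRNA pathway, meiotic prophase, pachytene and later spermatocytes, spermatids, Leydig cells, myoid cells, stroma, endothelium, macrophages and leukocytes, erythroid cells, the retinoid pathway, oocyte and granulosa cells, neurons, liver, skeletal muscle, housekeeping genes, olfactory and vomeronasal receptors, Hox and Rhox genes. Gcna and H1f8 were not found in the annotation and were left out.

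Overlap by at least 1 bp counted as shared and was set against 100 shuffles within chromosomes, or within peaks for footprints, with the seed 20. The smallest permutation p is then 0.0099. Chromosome X was ranked among the 19 autosomes and itself by an exact permutation test. Each gene list was tested against all other protein-coding genes by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Shares of genes carry exact (Clopper-Pearson) binomial 95% intervals. The height of a promoter is its tallest peak in the shorter list, or in the longer list where only the other replicate had a peak in the shorter one. List ratios of replicate 1 over replicate 2 were centred on the median gene and set against 10000 random lists matched on mean height in 20 bins. Motifs were scanned as consensus sequences in windows centred on peaks and in windows shifted by 1000 bp either way that overlapped no peak. A motif was called when both replicates had an odds ratio above 1.5 and an adjusted p under 0.05 by Fisher's exact test. In footprints, matches were compared with those of 10 permutations of the motif's letters.

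Named items followed a rule: for each list the 3 members with the tallest promoter peaks in both replicates and the first 2 by symbol without one, the 10 tallest shared peaks, the 3 promoters with the largest ratio each way, and the 5 motifs with the largest and 3 with the smallest odds ratios among those with at least 100 matches. A few items that the rule selects are left out of the text. Items named beyond it are said to have been chosen after their values were seen.

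Alternatives were the longer peak lists, 50% overlap, equal numbers of peaks, the taller peaks, promoters of 250 and 1000 bp, a single start per gene, random lists matched on CpG ratio, peaks outside promoters within 10 kb, other centring, a wider motif window, permutations keeping CG pairs, stricter false discovery rates, and leaving out each replicate. Dense runs (at least 10 peaks within 5 kb on either side), heights of the same overlapping peak, odds ratios relative to permuted letters, and the ratio of shared distal peaks with a motif against 1000 random peak sets were chosen after the data were examined.

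The steps were tested on simulated data. All 8 lists planted with more and all 7 with fewer promoter peaks were called and none of 8 others. The planted shares lay further from those of other genes than several shares reported here, so smaller differences were not covered. Planted ratios were recovered near their size, and 1 of 7 unshifted lists lay outside the 95% range. Of 30 motifs, 5 planted ones were called and 25 others were not. Planted motifs were far more frequent than rare ones such as ZBTB33 and NFI here. Simulated windows had evenly drawn bases, so differences in base composition between peaks and flanking windows were not simulated. For footprints, single comparisons were simulated, and 92 of 100 without a planted effect did not pass on the unadjusted p. The full rule for a call, with adjustment, odds ratio and both replicates, was not simulated there. The footprint simulation therefore gives no rate of false calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used.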

Results

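DNase-seq maps open chromatin, the DNA that the nuclease DNase I reaches and cuts in nuclei. It was applied to whole testis from 10-day-old males of the mouse strain B6CASTF1/J, the first-generation offspring of a cross between a laboratory strain and a strain of another mouse subspecies. All libraries belonged to 1 group, testis, with 2 biological replicates and no control group. The labels number the replicates' tissue as different males under a single donor identifier, and do not state whether tissue was pooled. Replicate 1 had 115361 peaks and replicate 2 had 117630 in the shorter of the 2 deposited peak lists of each library, covering 21.4 Mb and 22.9 Mb. The longer lists held 195352 and 191507 peaks. Read totals were not given in the sources used here, so the depth of each library is unknown. Peak heights were whole multiples of 0.00368 in replicate 1 and 0.00334 in replicate 2, and the lowest peak of each shorter list stood at 11 and 9 such steps. Median heights were 0.953 and 0.585. Coordinates are those of mm10, and each value that follows is that of a single library unless both are named.

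The replicates shared most of their tall peaks and fewer of their low ones. Of the peaks of replicate 1, 58.8% (67796 of 115361) overlapped a peak of replicate 2, and 57.7% of the peaks of replicate 2 (67901 of 117630) overlapped one of replicate 1. After shuffling within chromosomes the shares were 1.77% and 1.78% on average (one-sided permutation p = 0.0099 in each direction, the smallest that 100 shuffles can give). Of the taller 50% of peaks of replicates 1 and 2, 84.5% and 83.1% overlapped a peak among the taller 50% of the other replicate. Across the 67796 shared peaks, log2 height correlated between the replicates with Pearson r = 0.95 and Spearman rho = 0.94. This is a correlation across peaks, which are not independent replicates. The median shared peak was 1.48-fold higher in replicate 1, on the deposited scales, and 85.0% of shared peaks were higher there.

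Peaks without a partner differed between the replicates. In replicate 2, 44883 peaks (38.2%) overlapped no peak of either list of replicate 1, with a median height of 0.147. Of these, 56.9% lay in dense runs, defined after the data were examined as 10 or more peaks of the same list within 5 kb on either side. Replicate 1 had 24447 such unmatched peaks (21.2%), with a median height of 0.475 and 11.5% in dense runs. Without dense runs, 71.6% of the remaining 84392 peaks of replicate 2 and 56.3% of the remaining 107180 of replicate 1 were shared.

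The tallest shared peak lay on chromosome X at 169998241 to 169998400, in an intron of Mid1, with heights of 68.8 and 38.6 in replicates 1 and 2. The next lay on chromosome 9 at 123461921 to 123462080, in an exon of Lars2 (51.1 and 52.9), and on chromosome 17 at 39846781 to 39846880 (38.2 and 49.8), outside protein-coding genes. A peak on chromosome X at 143482981 to 143483140 was nearest to the start of Pak3, 35530 bp away (44.2 and 41.8). Of the 10 tallest, those in promoters belonged to Dynlt1b (45.6 and 34.4), Nup107 (51.1 and 29.0), Hjurp (49.8 and 23.5), Sugct (41.5 and 30.2) and Bahcc1 (49.3 and 19.3). Another lay in an exon of Cers5 on chromosome 15 (30.6 and 44.8). No step here removed repeated or multi-copy sequence, so such sites were not told apart from single-copy ones.

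Promoters held far more peaks than their share of the genome. Windows of 500 bp on either side of annotated starts of protein-coding transcripts held 22.7% of the peaks of replicate 1 (26155) and 20.2% of those of replicate 2 (23815), against 1.67% and 1.68% after shuffling. Exons held 8.99% and 8.40%, 2.26-fold and 2.08-fold the shuffled shares. Introns held 31.2% and 31.6%, and intergenic DNA 37.1% and 39.8%, all below the shuffled shares. Each of these differences had a one-sided permutation p of 0.0099, the smallest that 100 shuffles can give. Of 21853 protein-coding genes, 13956 (63.9%, exact binomial 95% interval 63.2 to 64.5%) had a promoter peak in both replicates, and 1374 (6.29%) had one in a single replicate. The intervals cover counting error over genes only.

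Chromosome X carried the fewest peaks per Mb of any chromosome but Y. Over peaks shared by the replicates its peaks were lower in both replicates. Its density was 18.4 peaks per Mb in replicate 1 and 12.8 in replicate 2, against autosome means of 46.2 (SD 9.98, n = 19 chromosomes, exact permutation p = 0.05) and 47.6 (SD 9.53, n = 19, exact permutation p = 0.05). The p is one-sided over 20 chromosomes and is the smallest that this design allows, so it could not pass below 0.05. X stood at 0.399 and 0.270 of the autosome mean. Among the taller 50% of peaks these were 0.265 and 0.268, and outside promoters 0.358 and 0.214. Chromosome Y had 0.599 and 0.752 peaks per Mb. Over all peaks, shared or not, the median height on X was 0.614 in replicate 1 and 0.585 in replicate 2, the latter equal to the median of that library.

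The deficit of X was present at promoters and away from them. Over peaks shared by the replicates, the median height on X was 0.571 of that on autosomes in replicate 1 and 0.567 in replicate 2 (1922 X peaks and 65835 autosomal peaks). At promoters it was 0.440 and 0.443 (749 and 20518 peaks), and at other peaks 0.575 and 0.588 (1173 and 45317 peaks). A promoter peak in both replicates was found for 481 of 948 X genes (50.7%) and for 13470 of 20722 autosomal genes (65.0%), an odds ratio of 0.555 (two-sided Fisher's exact test, p = 1.45e-18). Without olfactory receptor, vomeronasal receptor and Rhox genes the shares were 53.0% of 905 and 69.9% of 19266 (odds ratio 0.487, Fisher's exact test p = 4.68e-25). The height and gene comparisons of X were chosen after the data were examined. A male carries a single X, and these values were not adjusted for copy number.

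**Figure D1:**
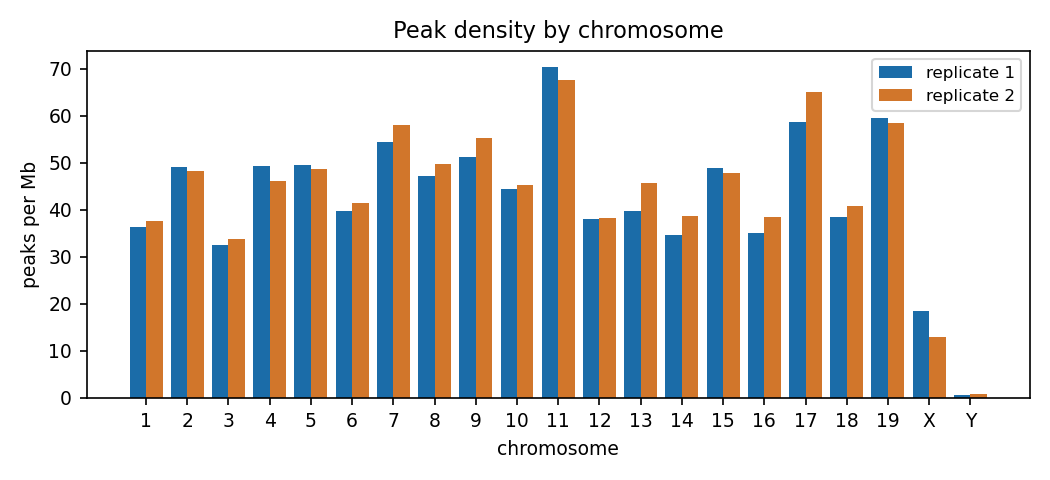
Peaks per Mb (vertical axis) on each mouse chromosome (horizontal axis) in the 2 testis replicates, from the shorter peak list of each library. Chromosome X stood at 18.4 and 12.8 peaks per Mb, below each of the 19 autosomes.

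Genes of Sertoli cells, of the germ line, of meiotic prophase and of peritubular myoid cells had promoter peaks more often than other protein-coding genes, and genes of spermatids, blood, liver and skeletal muscle less often. Of 23 lists fixed before the data were examined, 14 passed a Benjamini-Hochberg adjusted p of 0.05 by two-sided Fisher's exact test, 5 with more and 9 with fewer promoter peaks in both replicates. Genes served as the units, so the tests describe these libraries and not a population of mice. The other genes include olfactory receptor, vomeronasal receptor and Rhox genes, which rarely had a promoter peak. Leaving these families out raised the share of autosomal genes from 65.0% to 69.9%, and the list tests were not repeated without them. Promoters of different lists differ in CpG content, and against 10000 random lists matched on the promoter's CpG ratio 9 lists passed, not all of them the same lists. That result is given beside each list where it changed the call.

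Of 23 genes of Sertoli cells, the somatic cells that nurse the germ cells, 21 (91.3%) had a promoter peak in both replicates, against 63.8% of other genes (Fisher's exact test, adjusted p = 0.00896). The tallest were at Sox8 (8.43 and 5.62 in replicates 1 and 2; gene at chromosome 17, 25565892 to 25570686) and Gata4 (7.16 and 3.40), which encode transcription factors, and at Clu (7.28 and 5.59), which encodes the secreted protein clusterin. Rhox5 and Tsx, both on X, had none in either replicate. The excess was also present against CpG-matched lists (63.6% on average, adjusted p = 0.00131, permutation). Of 15 genes of peritubular myoid and smooth muscle cells, 14 (93.3%) had a promoter peak (Fisher's exact test, adjusted p = 0.0249), with the smooth muscle myosin gene Myh11 (7.05 and 5.04) and Itga8 (7.65 and 3.61) among the tallest, while Actg2 had none. Among 18 interstitial stroma genes, 15 had one (83.3%, Fisher's exact test, adjusted p = 0.198). This list passed against CpG-matched lists, whose mean was 51.1% (permutation, adjusted p = 0.00131). Gli1 (6.00 and 5.31), Pdgfra (6.53 and 3.30) and Fbln1 (5.50 and 2.25) were its tallest, and Lum and Mfap5 had no promoter peak. Without dense runs, the shares of the Sertoli and myoid lists were 78.3% and 80.0% and no longer passed (Fisher's exact test, adjusted p = 0.218 and 0.287). The myoid list also did not pass with the longer peak lists (adjusted p = 0.0797), in replicate 1 alone (adjusted p = 0.0702) or with a single start per gene (adjusted p = 0.062), all by Fisher's exact test.

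The Leydig and endothelial lists were not distinguished from other genes. Of 19 genes of Leydig cells and steroid synthesis, 12 (63.2%) had a promoter peak in both replicates (Fisher's exact test, adjusted p = 1). The tallest were at genes of general electron transfer and steroid reduction, Por (21 and 8.84), Fdxr (13.9 and 12.1) and Srd5a1 (14.4 and 11.6). Cyp11a1, which encodes the enzyme that starts steroid synthesis from cholesterol, and Akr1c14 had none. Of 17 endothelial genes, 9 (52.9%) had one (Fisher's exact test, adjusted p = 0.516), among them Egfl7 (5.12 and 2.77), the VEGF receptor gene Kdr (3.32 and 1.9598) and Sox18 (2.37 and 1.00), but not Emcn or Erg.

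Germ-cell lists ranged from high shares in the germ line and meiotic lists to a low share in spermatids. In the germ line and piRNA pathway list, 20 of 22 genes (90.9%) had a promoter peak in both replicates (Fisher's exact test, adjusted p = 0.013), led by the Tudor-domain genes Tdrd7 (26.4 and 14.2) and Tdrkh (11.7 and 5.34) and the RNA-binding protein gene Dazl (11.7 and 5.78). In the meiotic prophase list it was 27 of 30 (90.0%; Fisher's exact test, adjusted p = 0.00493). Its tallest were at the chaperone gene Hspa2 (19.6 and 11.5; chromosome 12, 76404176 to 76406938), at Prdm9 (14.8 and 10.0), which encodes the methyltransferase that places recombination hotspots, and at the crossover gene Msh5 (15.8 and 8.92). Neither list differed from CpG-matched lists, whose mean shares were 83.0% and 87.9% (permutation, adjusted p = 0.779 and 1). Counting a single start per gene, the germ line list no longer passed (77.3%, Fisher's exact test, adjusted p = 0.208), nor did the meiotic list without dense runs (80.0%, adjusted p = 0.0698).

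Of 23 genes of undifferentiated spermatogonia, 14 (60.9%) had a promoter peak in both replicates, which did not differ from other genes (Fisher's exact test, adjusted p = 0.867) and was below the 84.3% of CpG-matched lists (permutation, adjusted p = 0.00173). Etv5 (20.6 and 8.81), Id4 (14.3 and 5.39) and Foxo1 (11.2 and 5.33), which encode regulators of spermatogonial stem cells, had the tallest peaks, and Bcl6b and Nanos2 had none. In replicate 1 alone the share was 82.6% (Fisher's exact test, adjusted p = 0.295). Of 13 genes of differentiating spermatogonia, 10 (76.9%) had one (Fisher's exact test, adjusted p = 0.51). Kit (5.80 and 2.10), the receptor for stem cell factor, Dnmt3b (4.50 and 1.55) and Ccnd2 (3.15 and 2.18) were the tallest. In replicate 1 alone all 13 had one, and the list then passed (Fisher's exact test, adjusted p = 0.0254). Of 20 genes of pachytene and later spermatocytes, 14 (70.0%) had one in both replicates (Fisher's exact test, adjusted p = 0.71), led by Rfx2 (23.0 and 13.4), Tesmin (15 and 11.5) and Ybx2 (11.7 and 4.32), with none at Pgk2. In replicate 1 alone the share was 95% (Fisher's exact test, adjusted p = 0.0254).

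Of 30 spermatid genes, 10 (33.3%) had a promoter peak in both replicates, fewer than other genes (Fisher's exact test, adjusted p = 0.00252). The acrosomal genes Acr and Acrv1 had none. The tallest were at Oaz3 (18.1 and 7.05), Catsper2 (16.6 and 5.49) and Tssk6 (12.8 and 7.13). Oaz3 overlaps Tdrkh of the germ line list on chromosome 3, and their tallest promoter peaks differ in height. CpG-matched lists had a promoter peak in 36.6% of genes, and the spermatid list did not differ from them (permutation, adjusted p = 0.98).

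**Figure D2:**
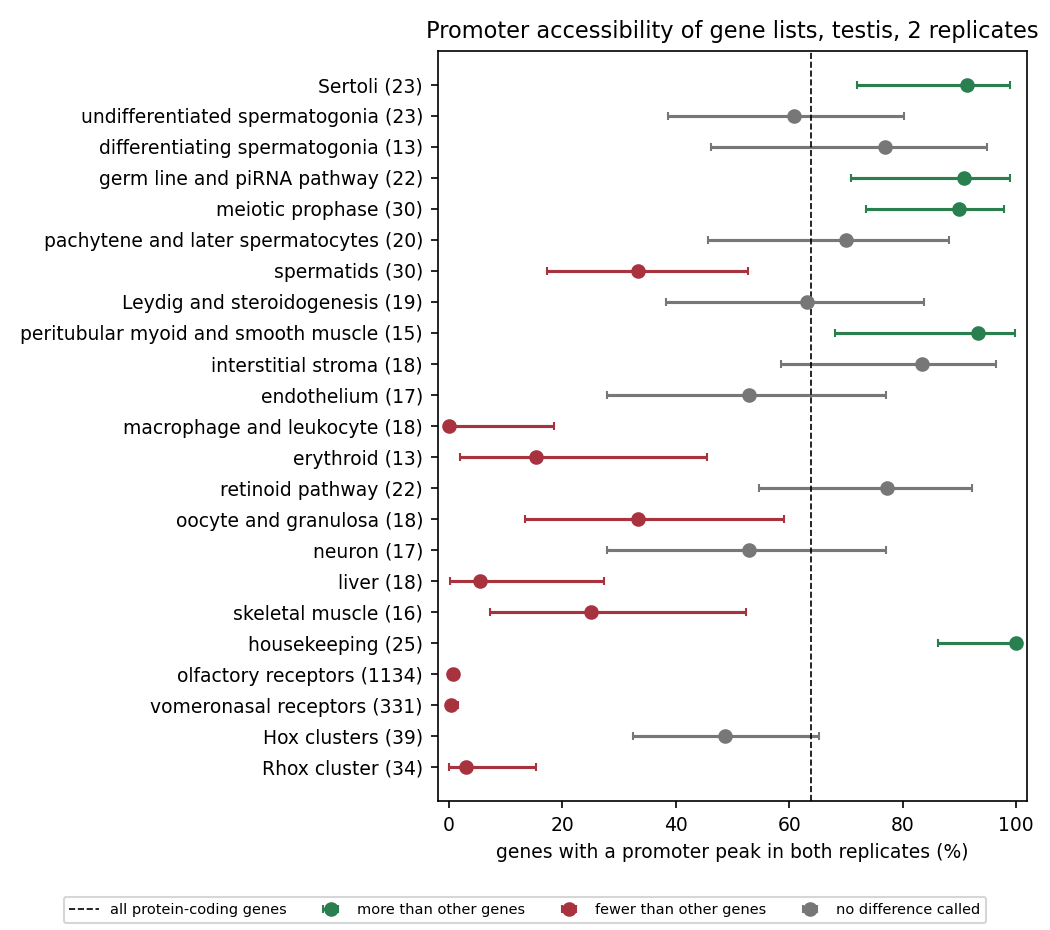
Share of the genes of each list with a promoter peak in both testis replicates (horizontal axis, percent) with exact binomial 95% intervals; the number of genes stands in brackets and the dashed line marks all protein-coding genes, 63.9%. Colours mark lists with more, fewer or no called difference by Fisher's exact test; 5 lists lay above and 9 below other genes.

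Most genes of the macrophage and leukocyte, erythroid, liver, skeletal muscle, and oocyte and granulosa lists did not have a promoter peak in both replicates. None of the 18 macrophage and leukocyte genes, Aif1 and C1qa among them, had a promoter peak in both replicates (exact binomial 95% interval 0 to 18.5%; Fisher's exact test, adjusted p = 6.27e-08). Of 18 liver genes only Ahsg (1.18 and 0.816) had one, and Alb and Ambp had none (Fisher's exact test, adjusted p = 1.65e-06). Of 13 erythroid genes, 2 had one, Epor (2.43 and 1.33) among them (Fisher's exact test, adjusted p = 0.00157), and Alas2 and Epb42 did not. Of 16 skeletal muscle genes, 4 had one (25%; Fisher's exact test, adjusted p = 0.00587), with the tallest at Mylpf (18.8 and 5.86), Pvalb (2.57 and 1.13) and Ryr1 (2.38 and 1.65) and none at Acta1 or Casq1. Of 18 oocyte and granulosa genes, 6 had one (33.3%; Fisher's exact test, adjusted p = 0.0207), among them Figla (3.96 and 1.12), Fst (2.13 and 0.860) and Wnt4 (1.88 and 1.23), but not Bmp15 or Gdf9. None of these 5 lists differed from CpG-matched lists (permutation, adjusted p from 0.253 in macrophages to 1 in erythroid genes). In replicate 1 alone, the oocyte and granulosa list (55.6%) and the muscle list (43.8%) no longer passed (Fisher's exact test, adjusted p = 0.254 and 0.0714). With the longer peak lists they did not pass either (Fisher's exact test, adjusted p = 0.0671 and 0.0818), nor did the oocyte and granulosa list with a single start per gene (adjusted p = 0.0576) or the muscle list with the wider promoter (adjusted p = 0.0522).

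Neuronal genes had a promoter peak in 9 of 17 (52.9%; Fisher's exact test, adjusted p = 0.516), led by Grin1 (5.03 and 2.35), Tubb3 (4.12 and 1.93) and Slc17a6 (3.91 and 1.58), with none at Neurod6. This was below CpG-matched lists at 77.0% (permutation, adjusted p = 0.00971). In replicate 1 alone the neuronal share was 94.1% (Fisher's exact test, adjusted p = 0.0521) and with the longer lists 82.4%, so the low share rests on replicate 2 and its shorter list. Retinoid pathway genes had one in 17 of 22 (77.3%; Fisher's exact test, adjusted p = 0.361), with the tallest at the receptor genes Rxrb (24.6 and 10.6) and Rara (8.13 and 4.92) and at Aldh1a2 (5.52 and 3.04), an enzyme that makes retinoic acid, and none at Crabp2 or Cyp26c1. All 25 housekeeping genes had one (Fisher's exact test, adjusted p = 8.69e-05; CpG-matched mean 95.3%, permutation, adjusted p = 0.836), the tallest at Vps29 (21.5 and 14.6), Psmb2 (24.0 and 11.9) and Actb (22.2 and 13.8).

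Genes of clustered families rarely had a promoter peak in both replicates, apart from the Hox genes. Of 1134 olfactory receptor genes, 9 (0.794%) had a promoter peak in both replicates, the tallest at Olfr373 (2.53 and 1.45), Olfr464 (2.42 and 0.916) and Olfr658 (1.37 and 0.816), and Olfr1 and Olfr10 had none. Of 331 vomeronasal receptor genes only Vmn1r4 (12.6 and 6.78) had one (Fisher's exact test, adjusted p = 3.74e-145), with none at Vmn1r10 or Vmn1r100, and of 34 genes of the X-linked Rhox cluster only Rhox8 (0.809 and 0.569; adjusted p = 4.20e-13), with none at Rhox1 or Rhox10. Single replicates gave more: replicate 1 alone had 11.8% of Rhox genes and 1.76% of olfactory receptors, and replicate 2 alone had 1.499% of olfactory and 0.604% of vomeronasal receptors. Of 39 Hox genes, 19 (48.7%) had one (Fisher's exact test, adjusted p = 0.0997), led by Hoxa4 (12.4 and 4.52), Hoxc10 (6.79 and 4.54) and Hoxd8 (7.10 and 3.01), with none at Hoxb2 and Hoxb3. In replicate 1 alone the Hox share was 84.6%, above that of other genes (Fisher's exact test, adjusted p = 0.0572). Without dense runs the Hox share was 33.3%, which passed as fewer (Fisher's exact test, adjusted p = 0.00136). The Hox share was below that of CpG-matched lists, 89.2% (permutation, adjusted p = 0.00115). Within 10 kb of a start but outside promoters, 35 of the 39 Hox genes (89.7%) had a peak, more than the 47.3% of other genes (Fisher's exact test, adjusted p = 2.91e-07).

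Promoters of germ line, meiotic, spermatogonial, pachytene and neuronal genes, but not of spermatid genes, were higher in replicate 1, and promoters of myoid and stromal genes were higher in replicate 2, once the general difference between the libraries was taken out. Over 14851 genes, promoter height was 1.97-fold higher in replicate 1 at the median (log2 0.98), and list values were centred on that median. Where a gene had a promoter peak in a single replicate of the shorter lists, the height of the other replicate was taken from its longer list. The germ line and piRNA list lay 1.09 above it on the log2 scale (2.14-fold; 20 of 21 genes above 0) and the meiotic prophase list 1.01 above it (2.01-fold; 24 of 30 genes), each higher than all 10000 random lists of the same size matched on mean height. Differentiating spermatogonia followed at 0.56 (10 of 13 genes; percentile 99.99), pachytene and later spermatocytes at 0.37 (10 of 16; percentile 99.9) and undifferentiated spermatogonia at 0.27 (12 of 17; percentile 99.4). The myoid list stood at -0.63 (1 of 14 genes above 0), lower than all random lists, and the stroma list at -0.53 (4 of 15; percentile 0.090). There is 1 library per replicate, so these percentiles describe the libraries and no test over replicates was made.

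Within the germ line and meiotic lists the shift was uneven. The 3 members of each list with the tallest promoters showed little or none of it. Tdrd7 stood at -0.08, Dazl at 0.04, Tdrkh at 0.15, Hspa2 at -0.21, Prdm9 at -0.42 and Msh5 at -0.15. Other members, named after their values were seen, were Taf7l (4.81 against 0.585, centred log2 2.06), Asz1 (3.08 against 0.405, 1.95), Tex12 (3.59 against 0.515, 1.82), Syce1 (5.71 against 0.826, 1.81) and Ddx4 (6.10 against 1.19, 1.38). The list medians were close to 0 for Sertoli genes (-0.04; 9 of 21 genes above 0; percentile 42.1), housekeeping genes (0.03; percentile 58.1) and spermatid genes (-0.05; percentile 33.7). They were -0.21 for Leydig genes (percentile 10.3), -0.25 for endothelium (percentile 18.4), -0.23 for Hox genes (percentile 8.14), -0.33 for olfactory receptors (percentile 35.3), 0.12 for the retinoid pathway (percentile 92.1), 0.18 for oocyte and granulosa genes (percentile 95.1), 0.06 for skeletal muscle (percentile 67.2) and 0.20 for neuronal genes (10 of 14 above 0; percentile 98.3), which lay above the central 95% of its random lists. With heights of the same overlapping peak in both replicates, neuronal genes moved to percentile 92.1 and the pachytene list to 97.52, close to the edge of the central 95%. Scaling each library by its summed height in place of the median gene raised each list by the same amount, from a centre of 0.98 to 0.83, which turned the Sertoli and spermatid medians to 0.12 and 0.10.

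The rule for single promoters named Slc18a1 (29.2 against 0.642), Tmem233 (0.684 against 0.0368) and Cdc42bpa (8.71 against 1.01) as the most shifted to replicate 1. At Slc18a1 the overlapping peak of replicate 2 was 15.9 high and lay outside the promoter window, and with that peak the centred log2 ratio was -0.11. At Cdc42bpa the overlapping peak was 3.55 high, with a ratio of 0.31. At Tmem233 the promoter peaks of the replicates did not overlap, so its heights are those of different peaks. Its height in replicate 2 was also close to the lowest of that list, 0.0301. The most shifted to replicate 2 were Gm11168 (0.206 against 0.522), 4931408C20Rik (0.478 against 1.14) and Slc39a5 (0.177 against 0.415). Repeated sequence was not removed here either.

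**Figure D3:**
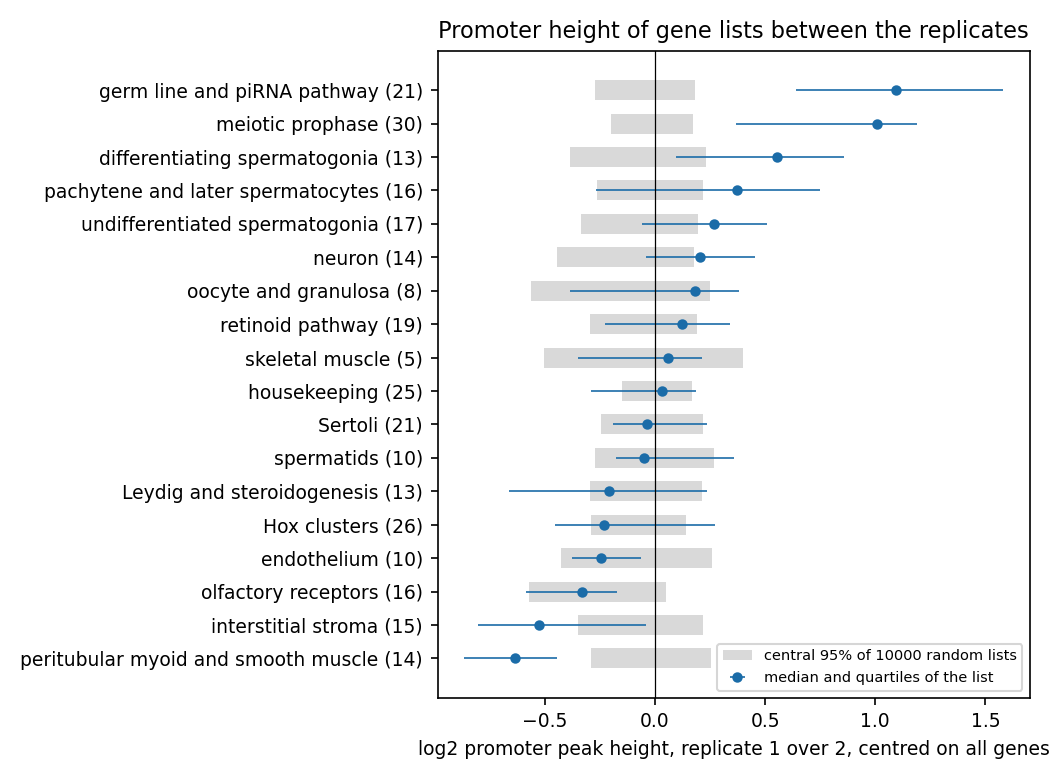
Median and quartiles over the genes of each list of log2 promoter peak height, replicate 1 over replicate 2, centred on all genes (horizontal axis, log2); the number of genes stands in brackets and grey bars span the central 95% of 10000 random lists matched on mean height. Germ line genes (1.09) and meiotic genes (1.01) lay to the right of their bars and myoid genes (-0.63) to the left.

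The motifs with the largest odds ratios were partly the same at promoter and distal peaks, and partly different. The difference between these classes was not tested. Of 30 motifs fixed before the data were examined, 13 were more frequent in windows centred on peaks than in windows 1000 bp away in both replicates, with an odds ratio above 1.5 and a Benjamini-Hochberg adjusted p under 0.05 by Fisher's exact test. Among promoter peaks 14 passed, and among distal peaks 13. At promoters, among motifs with 100 or more matches, the largest odds ratios were those of ZBTB33 (124 and 118 peaks, none in flanking windows), YY1 (317 and 302), NRF1 (175 and 97.3), CREB (20.8 and 17.4) and WT1/EGR (18.2 and 19.99). Relative to permutations of the motif's letters, an alternative chosen after the data were examined, the mean log2 odds ratio of NRF1 fell from 6.85 to 3.69 and that of WT1/EGR from 4.22 to 1.19. The SP/KLF motif, a GC box named after its values were seen, was in 13.5% and 14.4% of promoter peaks, against 0.892% and 0.887% of flanking windows. The smallest were those of GATA (0.315 and 0.254), TEAD (0.335 and 0.348) and AP-1 (0.561 and 0.597), all below 1 (Fisher's exact test, adjusted p at most 1.97e-16). Relative to permuted letters they were not below: mean log2 values were 0.14, 0.19 and 0.33.

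Distal peaks were led by the insulator protein CTCF, whose motif was in 6.50% and 5.47% of them (5801 and 5130 peaks), with odds ratios of 118 and 87.0. NFI followed (39.1 and 45.9), then WT1/EGR (10.3 and 5.89), SP/KLF (4.66 and 4.22) and CREB (3.61 and 2.76). The smallest were those of RUNX (0.684 and 0.763), MEF2 (0.724 and 0.552) and POU/OCT (0.609 and 0.519), all below 1 (Fisher's exact test, adjusted p at most 0.000374). Relative to permuted letters these turned to 0.19, 0.79 and 0.14 on the log2 scale, and 10 distal motifs were counted in place of 13. That count joined the excess over permuted letters, itself not tested, with the p of the comparison with flanking windows. It includes MEF2, whose odds ratios were below 1, so it is not a count of motifs more frequent in peaks. Over all peaks, REST, a repressor of neuronal genes, had its motif in 121 and 105 peaks, against none of the flanking windows of replicate 1 and 1 of replicate 2. A pair of motifs differed between the replicates and is named after its values were seen: the DMRT core motif, in 1.54% of distal peaks in replicate 1 and 0.486% in replicate 2 (odds ratios 3.08 and 0.899), and NRF1 (24.6 and 4.58).

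Footprints, short stretches protected from cutting within open DNA, recurred between the replicates beyond chance. The authors' lists held 509839 footprints in replicate 1 and 439517 in replicate 2, with a median width of 11 bp in each. Of footprints wholly inside a peak, 57.9% in replicate 1 and 63.0% in replicate 2 overlapped a footprint of the other replicate, against 43% and 47.7% when footprints were shuffled within their own peak (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give). With at least 50% of the footprint covered, the shares were 51.6% and 57.5%, against 25.1% and 28.5%. At least 1 footprint overlapped 88.6% of the peaks of replicate 1 and 76.5% of those of replicate 2.

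Matches of 11 of the 30 motifs fell in footprints more often than matches of permutations of their letters. CTCF matches lay in footprints in 97.2% and 97.6% of cases, against 31.0% and 27.9% for permuted letters (odds ratios 76.4 and 103; Fisher's exact test, adjusted p at most 1.24e-279). The shares were 94.6% and 93.8% for NFI, 97.49% and 91.8% for NRF1, and 75.6% and 72.0% for ZBTB33. The motif of NR5A1, the steroidogenic factor of Sertoli and Leydig cells, is named after its values were seen and had 43.9% and 23.4% of its matches in footprints, against 18.6% and 13.3%. REST matches lay in footprints in 100% and 98.1% of cases, but its permuted letters had no match in replicate 1 and no test could be made there. Among the lowest were AP-1 (13.1% and 9.68%, against 17.0% and 12.6%) and MYB (20.1% and 15.4%, against 24.2% and 19.07%), each below its permuted letters in both replicates.

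The per-base cut-rate lists covered similar lengths in the replicates and, at their full threshold of 0.05, lay mostly outside the shorter peak lists. They held 34754890 entries in replicate 1 and 31863495 in replicate 2, with false discovery rates from 0 to just under 0.05, over 56.1 Mb and 55.7 Mb. Of these bases, 38.2% and 41.1% lay in peaks of the shorter list and 61.7% and 63.8% in peaks of the longer list. At 0.001 or less, 60.5% and 63.9% lay in peaks of the shorter list. The bases listed in both replicates came to 34.3 Mb, 61.1% and 61.6% of the lists. A false discovery rate of 0.001 or less was reached in 99.7% and 99.6% of shorter-list peaks, and in 61.0% and 62.9% of longer-list peaks.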

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

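Chosen after the result was seen were the definition of dense runs and the DMRT pattern itself, with its comparison with random peak sets. So were the tests of a general loss of germ cells, of the lists' own non-promoter peaks and of height inside dense runs. Expected outcomes of the other tests of explanations were set beforehand. Those for dense runs and DMRT peaks still rest on these later choices. A signal appeared in data that the peak comparisons do not use. Of all bases at a false discovery rate of at most 0.001, 39.1% in replicate 1 (13.7 Mb) and 35.5% in replicate 2 (12.6 Mb) lay outside both peak lists. There is no control sample to set them against.

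The germ line and meiotic promoters were higher in replicate 1. After a fit on promoter CpG ratio, GC content and height over all genes, which took up 18.8% of the variance, their median log2 ratio was 1.11 (n = 51, 43 above 0), against 1.05 before, so these do not account for it. A lower share of germ cells in replicate 2 would raise all other cell types alike, if each promoter followed its own cell type only. Sertoli genes stood 0.55 (log2) above myoid and stroma genes (permutation p = 0.0008). This contrast was chosen after the list medians were seen, and its p is over genes of 1 library per replicate. The promoters also differed in CpG ratio (medians 0.564, 0.360 and 0.412 for Sertoli, myoid and stroma genes). The contrast therefore cannot decide, and a lower share of germ cells stays open. The tallest non-promoter peaks within 10 kb of meiotic genes were also higher (0.38, 9 of 10 above 0, percentile 98.7 of random lists), but so were those of Sertoli (0.41) and neuronal genes (0.39, 13 of 13), so this shift is not particular to meiotic genes. Those of germ line genes were not higher (-0.22, 3 of 8, percentile 15.1), and a difference confined to promoters stays open for that list. In these comparisons the tallest peak was taken in each replicate separately, so a ratio may compare different sites. A mixture of several cell types or a stage that differed between the replicates may be involved and stays open. The design has 1 group, and beyond the share of germ cells no biological explanation was tested.

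Of the peaks of replicate 2 without a partner, 56.9% lay in dense runs. In that library the 10th percentile of height inside the runs was 0.545 of that outside, but in replicate 1, with 7.09% of its peaks in runs, it was 0.253. A lower height threshold inside runs therefore does not set the replicates apart by these values and stays open. The runs had 0.525 of the annotated starts per Mb of other peaks and a GC content of 46.8% against 46.6%. This was the outcome set beforehand against gene-dense, GC-rich DNA. However, 26.4% of the peaks of replicate 2 outside runs lay in promoters, which raises the starts counted around them. The runs were not compared with the whole genome, so gene-dense, GC-rich DNA stays open as a reason. For a copy gain in replicate 2, the median log2 ratio of replicate 2 over 1 was 0.39 higher for shared peaks inside the runs than elsewhere (bootstrap 95% interval 0.37 to 0.41). This lay between the values set beforehand for and against a copy gain, so it cannot be told apart from other causes. The bootstrap drew single peaks, which cluster in 1733 runs, so its interval may be too narrow. The runs were also defined by the peaks of replicate 2, so the comparison was not independent of that library. Beyond copy gain no biological explanation was tested.

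Distal peaks with the DMRT core motif were higher in replicate 1 than other shared distal peaks. Log2 ratios here were centred on the median of all shared distal peaks. The median of the 297 shared peaks with the motif was 0.44, and 225 of them were above 0. Loss of weak peaks in replicate 2 would leave shared peaks of like height unmoved, but random sets matched on height lay between -0.06 and 0.07. The 0.44 set against them is the value that showed the pattern, so this is no separate test of that explanation. Base composition would move peaks with permuted letters too, but their median was -0.06 (904 peaks), a share of -0.137 of the motif's value. Which DMRT factor or cell type may be involved was not tested, and no biological explanation was tested.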

How the results depend on the processing

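Tests without dense runs were chosen after the results were seen. For main outcomes, 82 alternatives kept the reported outcome. That means the same direction and side of the threshold, a count within 1.5 times the reported one, or an untested value within its spread. Values could still differ. Of the taller peaks of replicate 1, 84.5% overlapped the taller peaks of replicate 2, against 58.8% with all peaks of both shorter lists. Another 20 untested values were labelled as moved. Those at stricter false discovery rates were so labelled by rule, with no spread to set them against. The others moved beyond their spread, which for r and rho was small. A further 6 counts fell below the range set for counts. Promoter peak shares of single lists kept their call under 166 alternatives, while 26 no longer passed, 9 newly passed and 6 turned; lists without a call could change sides. Scaling by summed height shifts every height ratio alike and tests no list. With the same peak in both replicates, also chosen later, oocyte (-0.08) and muscle (-0.08) ratios changed sign. With it, 5 in place of 6 lists lay above the random range. The cause of the changes below was not tested. No paired analysis was possible because there is 1 group, with 1 library per replicate.

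Pearson r of shared heights was 0.948 with the longer lists and with reciprocal overlap and 0.939 without dense runs; Spearman rho was 0.930 and 0.924. The share of genes with a promoter peak was 69.0% with the longer lists, 62.2% and 65.3% with promoters of 250 and 1000 bp, 59.4% with a single start per gene, 61.6% without dense runs, and 64.8 to 69.2% with each replicate left out.

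Called lists numbered 9 against CpG-matched lists and 7 for peaks outside promoters within 10 kb. Those with more peaks fell to 3 with a single start per gene, 2 without dense runs and 3 against CpG-matched lists, and those with fewer to 3 within 10 kb. Within 10 kb, 6 lists with a call in either region had a share that moved to the other side of that of other genes. They were the germ line (36.4%), meiotic (33.3%), macrophage (50%), oocyte (55.6%), muscle (68.8%) and Hox (89.7%) lists. Lists without a call in either region, such as the neuronal list (52.9% at promoters, 76.5% within 10 kb), could also change sides. Of the 6, only Hox genes passed within 10 kb (adjusted p = 2.91e-07, Fisher's exact test). The other 5 had no call there, and the region itself differed.

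By construction, stricter false discovery rates gave shorter lists: at 0.01, 44.1 and 44.4 Mb with 48.6% and 51.7% in peaks, and at 0.001, 35.2 and 35.4 Mb with 60.5% and 63.9%. Unknown depth limits what the low peaks show.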

Other observations

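All values in this part were computed after the results were seen. Of distal peaks with the DMRT core motif, 21.7% of those of replicate 1 were shared with replicate 2, against 52.1% of all its distal peaks, and 57.2% of those of replicate 2, against 49.7%. For NRF1 the shares were 23.2% and 91.2%, and for CTCF 86.3% and 97.52%.

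Log2 ratios of replicate 1 over 2 were centred on the median of the 46520 shared distal peaks. ETS (0.36), WT1/EGR (0.31), GATA (0.12), NR5A1 (0.10) and, barely, NFY (0.03) were among the other motifs above the range of matched random sets, towards replicate 1. Below that range lay NFI (-0.19, 44 of 127 peaks above 0), RUNX (-0.13), SRF (-0.06), AP-1 (-0.05) and CTCF (0.01, against 0.08 to 0.11). Before centring, the median of all shared peaks was 1.48-fold higher in replicate 1, so a value below 0 need not mean a higher peak in replicate 2.

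The tallest non-promoter peaks within 10 kb of Sertoli genes stood at 0.41 (13 of 18 above 0, percentile 99.87), those of myoid genes at -0.15 (percentile 9.60) and those of stroma genes at -0.02 (percentile 44.4). Each replicate's own tallest peak was used, which need not be the same site in both.

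The longest dense run of replicate 2 lay on chromosome 4 at 42865001 to 42937940 (72.9 kb), with 81 peaks in replicate 2 and 10 in replicate 1, around the starts of Fam205c and Phf24. The next, on chromosome 10 at 79521567 to 79592376 around the starts of Mier2, Plpp2 and Theg, held 92 and 59. The third, on chromosome 15 at 36437441 to 36506040 around the start of Ankrd46, held 100 and 8.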
